A study of Mus musculus with 16 samples.

How the data were processed

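RNA of CD31-sorted endothelial cells from liver and lung of adult mice was sequenced in 16 libraries, 4 for each combination of tissue and genotype. Cells were labelled with a fluorescent CD31 antibody and sorted after mechanical dissociation; libraries were made from 2 ng of RNA with an Illumina TruSeq kit and read as 100 bp pairs on an Illumina sequencer, per the labels' protocols. The submitters' processing notes name TopHat2 2.0.11, Bowtie2 2.2.1, SAMtools 0.1.19, HTSeq 0.6.1 and DESeq2, and the genome build mm9; the annotation and the strand setting are not given in the sources used here. Reads of overlapping, antisense or near-identical genes, such as Abcb1a or Serpinb1a and their paralogs, could not be told apart from the tables, so their values carry that uncertainty. No coordinates are given, since the reference used for gene names and neighbours was GRCm38.p6 and not mm9.

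The authors deposited raw read counts per gene for every library, whole numbers with no normalisation, per the file headers and the values. The authors' comparison tables also hold a signal column, the mean of normalised counts over the 8 libraries of a tissue, per the file headers. Their log2 fold changes and standard errors, the Wald score, and the p-value and its adjusted form are the authors' own, deposited per tissue, and were used only where the authors' deposited table is named. A further 16 columns of deposited CPM values were not used.

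Each table held 37991 gene entries. The line holding the column sum was left out of library sizes and tests, 3750 entries that share a symbol with another were kept under their own identifiers, and 39 liver and 12 lung entries without a matching identifier were left out. No 2 libraries of a group agreed within sampling noise. The labels describe 4 biological samples per condition.

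Genotypes were compared within each tissue by edgeR 4.0.16 (R 4.3.3) with TMM scaling, filterByExpr (minimum count 10, minimum total 15) and the quasi-likelihood test without a block, and adjusted by Benjamini-Hochberg with a threshold of 0.05. The tissue difference was the interaction contrast over all 16 libraries, and lung control was compared with liver control over 8. CPM values are scaled by TMM within a comparison; levels printed for lung against liver control come from that comparison's own scaling. Fold changes of genes with 0 reads in a group were computed against a floor of 3 reads over the group, which covers counting error only. Fold changes used a prior count of 0.125.

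The replicate letters (B, E, F and G in liver; B, E, F and D in lung) occur in both genotypes, and their meaning is not stated in the labels. Deviations from the group means of same-letter libraries correlated at 0.29, 0.238, 0.198 and 0.171 in liver (B, E, F, G) and at 0.119, 0.188, 0.18 and 0.11 in lung (B, E, F, D), across genes. Every library correlated best with the library of its own letter, and all 8 pairs were of 1 sex by Xist and Y-linked transcripts. The letters were therefore taken to pair the libraries within a tissue, and the fit with the letter as an additive block is given as the paired fit for the counts of genes and for many of the named genes and lists. Between tissues, same-letter libraries correlated at -0.0125 to 0.0573, and the letters were not used to pair liver with lung. This does not show that they came from different mice, which the labels do not state. Fits over both tissues treated the 8 pairs as independent, though B, E and F may stand for the same mice in both. The block over B, E and F for the control comparison is only an alternative.

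Gene lists, 23 of endothelial responses and 22 of markers of other cells or of sample quality, were fixed before the data were examined, as were the tests, the comparisons and most alternatives. Lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01, beside an estimated correlation and fry, and adjusted over all lists of a comparison. Named genes followed a fixed rule: Ctnnb1 first; per tissue the 8 largest rises and 8 largest falls among called genes in which all GOF libraries lay on 1 side of all controls and the higher group averaged at least 50 reads; up to 4 called members of each response list; 10 endothelial genes always given; and for the tissue difference the 6 smallest adjusted p in each direction. Because 5 liver genes and 0 lung genes passed without pairing, the rule was applied to the paired fit. An item that the rule names for the tissue difference is not reported here. In lung control against liver control, the genes named were chosen among the largest folds and list members after their values were seen.

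The scripts were tested on simulated counts with 200 genes changed by log2 0.5, 1 or 2. For liver without pairing (14666 genes) 0%, 18% and 60% were recovered, and 0 of 47 calls were false; in pairs 14.5%, 60.7% and 76.7%, with 6 of 98 calls false. For lung (14709 genes) the shares were 0%, 14.8% and 64.5% without pairing (0 of 49 false) and 11.3%, 54.1% and 74.2% in pairs (4 of 90 false). Paired DESeq2 1.42.0 gave 32 false among 136 calls in liver and 46 among 149 in lung. For the tissue difference (16368 genes) 0%, 3.4% and 38.3% were recovered without pairing and 3.2%, 27.6% and 55% in pairs (4 of 55 false). Changes of log2 0.5 were thus mostly out of reach at 4 libraries per group.

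Alternatives were DESeq2, DESeq2 size factors in edgeR, quantile normalisation or log2 values with limma, no filter, a filter 5 times higher, other prior counts, a threshold of 0.01, the replicate block and leaving out each library. Chosen after the data were examined were robust edgeR, leaving out both B libraries in liver or both E libraries in lung, the same alternatives with the block kept, and the averaged effect over both tissues. Other splits of the libraries were enumerated, or 100 drawn where there were more.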

Results

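Messenger RNA was sequenced from endothelial cells of adult mouse liver and lung, sorted by their surface CD31, an endothelial adhesion molecule. In the experimental mice an endothelial Cre recombinase driven by the VE-cadherin promoter switched on a stabilised, activated form of beta-catenin, the transcriptional effector of canonical Wnt signalling. These libraries are called GOF. Controls carried the activatable beta-catenin allele without the Cre transgene. GOF and control mice thus differed in the Cre transgene as well as in activated beta-catenin, and effects of the one and the other cannot be told apart here. There were 4 groups of 4 libraries (liver control, liver GOF, lung control and lung GOF), 16 in all. Total counts per library lay between 22815467 and 37127150, and between 15531 and 17891 genes had at least 1 read. The comparisons ask how activated beta-catenin changed the endothelial transcriptome in each tissue, whether the change differed between the tissues, and how control cells of both tissues differed.

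Transcripts of Ctnnb1, the gene for beta-catenin, did not differ between genotypes in either tissue. In liver Ctnnb1 (ENSMUSG00000006932) stood at 829 ± 87.0 CPM in control and 772 ± 69.9 CPM in GOF (SD, n = 4 each), a log2 fold change of -0.10 ± 0.144 (SE). In lung it stood at 661 ± 46.5 and 653 ± 66.3 CPM, a log2 fold change of -0.02 ± 0.145, which turned to 0.04 with quantile normalisation. Whether the transcript of the activated allele is counted within Ctnnb1 is not given in the sources used here, so this gene does not check the labels.

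In liver endothelial cells, Tcf7, a Wnt target, and 4 other genes were higher in GOF in the test without pairing. Tcf7, which encodes a DNA-binding partner of beta-catenin, rose from 3.58 ± 1.32 to 34.4 ± 12.4 CPM (SD, n = 4 each; log2 fold change 3.27 ± 0.346 SE). Kif21b, a kinesin motor, rose from 6.91 ± 0.821 to 33.4 ± 5.17 CPM, and Atp10a, a phospholipid flippase, from 13.3 ± 2.81 to 47.2 ± 13.0 CPM. The transcription factor Sox4 rose from 22.5 ± 5.76 to 68.9 ± 12.4 CPM and Apln, the apelin peptide of sprouting endothelium, from 14.1 ± 0.95 to 37.9 ± 7.15 CPM. Each of these 5 genes was higher in GOF in 4 of 4 same-letter pairs. They were the genes called by edgeR's quasi-likelihood test without pairing, at a Benjamini-Hochberg adjusted p under 0.05 among 15555 tested genes. Of these, 1010 genes had an unadjusted p under 0.05, where 778 were expected. Kif21b had the smallest adjusted p, 0.00192, and stayed past the threshold in 20 of 20 alternatives. Tcf7 did so in 16 of 20, Atp10a in 15, Apln in 14 and Sox4 in 13; the calls of all 4 were lost without control E, control F or GOF G. Without control G those of Atp10a, Apln and Sox4 were lost, without GOF F those of Apln and Sox4, and without GOF B that of Sox4. Over the alternatives the log2 fold change lay between 3.044 and 3.504 for Tcf7, 1.651 and 1.976 for Atp10a, 1.357 and 1.745 for Sox4, and 1.326 and 1.54 for Apln.

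With the replicate letter as a block, which pairs each GOF library with the control library of the same letter, 401 liver genes passed, 240 higher and 161 lower. The 8 largest rises under the naming rule included Nckap5 at a paired log2 fold change of 5.05 ± 0.785 (SE, 4 pairs), Ptn, the heparin-binding growth factor pleiotrophin, at 4.57 ± 0.743, and Scin, an actin-severing protein, at 3.80 ± 0.513. Tcf7 stood at 3.26 ± 0.242, Dkk2, a secreted Wnt modulator, at 2.82 ± 0.258, Mfsd7c at 2.27 ± 0.321 and Kif21b at 2.26 ± 0.192. The calcium channel gene Cacna1e had 0 reads in the 4 controls and 403 in GOF, at least 138-fold higher against a floor of 3 reads over the group. The largest falls were those of Bcan, a proteoglycan core protein (-2.98 ± 0.416), Ifitm1 (-2.00 ± 0.419), Plekha6 (-1.71 ± 0.232), Upb1 (-1.57 ± 0.354), Wfdc1 (-1.57 ± 0.31), Fjx1 (-1.54 ± 0.329), Arg1, the urea-cycle arginase of periportal hepatocytes (-1.50 ± 0.235), and Gpc1, a glypican (-1.47 ± 0.276). The count of 5 without pairing became 1 without control E, control F or GOF G, 3 without control G or GOF F, and 12 without GOF E. The paired count of 401 became 261 without the E pair and 256 without the F pair. DESeq2 called 150 genes without pairing, 99 higher and 51 lower. The paired calls of Upb1 (-1.657 to -1.527 over its alternatives) and Fjx1 (-1.653 to -1.454) were lost on leaving out any of the 4 pairs. The call of Ifitm1 (-2.265 to -1.603) was lost without E, F or G, that of Wfdc1 (-1.595 to -1.524) without B, F or G, that of Gpc1 (-1.633 to -1.123) without E and that of Cacna1e without B. Robust edgeR ended the call of Ptn (3.902 to 5.443).

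Some of the liver changes were in gene groups fixed before the data were examined. Among Wnt target and feedback genes, 5 of 17 tested members rose in the paired fit, none fell, and 16 of 17 had a positive fold change (5 higher, adjusted over the list alone). Axin2, a feedback inhibitor and standard Wnt reporter, went from 10.1 ± 2.91 to 43.7 ± 21.2 CPM (paired log2 fold change 2.03 ± 0.168, SE) and Sp5, a Wnt-induced transcription factor, from 3.64 ± 0.498 to 9.95 ± 5.06 CPM (1.34 ± 0.308), a call lost on leaving out any of the 4 pairs (1.113 to 1.483 over its alternatives). Lef1 stood at 0.348 ± 0.384 and 1.37 ± 1.37 CPM and did not pass. The list was higher by camera without pairing (adjusted p = 6.29e-10; adjusted p = 0.206 with an estimated correlation) and with it (2.09e-13; 0.303). Of 37 tested genes enriched in endothelium of the central nervous system, 4 rose and 1 fell in the paired fit (6 and 3 adjusted over the list alone). Abcb1a, the P-glycoprotein efflux pump of the blood-brain barrier, rose from 28.1 ± 7.68 to 130 ± 56.9 CPM (2.14 ± 0.195). So did Abcg2, another efflux pump (0.58 ± 0.106), and Cgnl1, a junctional scaffold (0.67 ± 0.104). Pltp, a phospholipid transfer protein, fell by 0.56 on the log2 scale. Other barrier genes did not pass: Cldn5 was at 0.33 ± 0.0874, the glucose transporter Slc2a1 at -0.02 ± 0.153 and Mfsd2a at 1.69 ± 1.84. Control B held Mfsd2a at 2.28 CPM and the other controls at 0 to 0.209 CPM, and its unpaired fold change lay between -0.4105 (without GOF B) and 3.441 (without control B). Camera gave adjusted p = 0.0328 for this list without pairing and 0.043 with it (0.338 and 0.303 with an estimated correlation). The call without pairing was lost without control E (0.197), control F (0.075), control G (0.0844), GOF B (0.209) or GOF G (0.0502). The call of Pltp (-0.6755 to -0.4821 over its alternatives) was lost without the B, E or G pair.

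Some genes typical of liver endothelium fell, and most members of their lists did not pass. Among angiocrine and pericentral endothelial genes, 5 of 17 fell and 1 rose in the paired fit (8 and 1 adjusted over the list alone), and camera placed the list lower (adjusted p = 3.59e-07; 0.303 with an estimated correlation). Wnt2 fell from 465 ± 95.5 to 245 ± 69.4 CPM (SD, n = 4 each; -0.95 ± 0.0897) and Wnt9b from 889 ± 232 to 450 ± 156 CPM (-1.001 ± 0.147). Both encode Wnt ligands that central-vein and sinusoidal endothelium supply to hepatocytes. Fabp4, a fatty acid binding protein, fell from 1050 ± 156 to 624 ± 127 CPM, in 4 of 4 pairs. Of 24 sinusoidal genes 4 fell and none rose (7 and 1 adjusted over the list alone; camera adjusted p = 0.000168, 0.49 with an estimated correlation), among them Lyve1, a hyaluronan receptor (-0.78 ± 0.0977), the membrane-trafficking protein Ehd3 (-0.77 ± 0.118), the lectin Clec4g (-0.63 ± 0.141) and Ctsl (-0.41 ± 0.0831). The calls of Clec4g (-0.8052 to -0.4445 over its alternatives) and Ctsl (-0.4681 to -0.3681) were lost without the B, E or F pair, and that of Clec4g also with limma, quantile normalisation and robust edgeR. Plvap, the diaphragm protein of fenestrae, fell from 2388 ± 523 to 1509 ± 319 CPM (-0.66 ± 0.0833) and was 1 of the 2 members lower among 13 fenestration and caveolae genes. Of 15 fatty acid handling genes 3 fell, including Fabp5 (-1.001 ± 0.155) (6 adjusted over the list alone; camera adjusted p = 1.71e-05, 0.303 with an estimated correlation).

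Some adhesion molecules for leukocytes rose in liver. Of 17 leukocyte adhesion and cytokine genes, 6 rose in the paired fit and all 17 had a positive fold change (7 adjusted over the list alone; camera adjusted p = 4.09e-08, 0.303 with an estimated correlation). Vcam1 rose from 1331 ± 503 to 2082 ± 848 CPM (SD, n = 4 each), E-selectin (Sele) from 1338 ± 675 to 2313 ± 1070 CPM and P-selectin (Selp) from 2031 ± 1030 to 3009 ± 1650 CPM, each higher in 4 of 4 pairs, and the chemokine Cxcl2 had a paired log2 fold change of 0.64 ± 0.144. Venous genes moved both ways, with 2 of 14 higher (Vcam1, Selp) and 4 lower, among them Amigo2 (-0.69 ± 0.116), Car8 (-0.68 ± 0.0906) and Prss23 (-0.77 ± 0.115). In the arterial list the kinase Bmx rose (1.10 ± 0.0922) and the connexin Gja4 fell (-0.48 ± 0.0865) among 20. Of 20 tip cell and VEGF genes 3 rose: Apln, Cd34 (1.17 ± 0.108) and Plaur, the urokinase receptor (0.88 ± 0.11). Plat, the tissue plasminogen activator, rose from 70.0 ± 20.1 to 200 ± 51.8 CPM, and prostaglandin synthase Ptgs1 fell (-0.54 ± 0.11). Tgfb2 (0.85 ± 0.0972), the laminin chain Lama5 (0.68 ± 0.15) and the death receptor Eda2r, a p53 target (1.80 ± 0.227), rose. The call of Cxcl2 (0.4955 to 0.7936 over its alternatives) was lost without the E, F or G pair, that of Ptgs1 (-0.6476 to -0.4241) without B, F or G, that of Lama5 (0.437 to 0.7847) without B or E, with limma trend and with robust edgeR, and that of Gja4 (-0.5217 to -0.4242) without F. The general endothelial genes Pecam1 (-0.11 ± 0.076), Cdh5 (0.21 ± 0.0736), Vwf (0.30 ± 0.0809) and Sox17 (0.29 ± 0.141) did not pass, and 0 of 22 pan-endothelial members did. Of the 23 response lists 13 were called by camera in the paired fit, and 0 of them with an estimated correlation (smallest adjusted p 0.303).

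Markers of other liver cells moved with the genotype in the same libraries. In the paired fit, 5 of 17 tested marker lists of other cells were lower in GOF and 0 were higher by camera. The median log2 fold change was -1.24 for mesothelial, -0.82 for periportal hepatocyte, -0.55 for hepatocyte, -0.66 for fibroblast and -1.01 for cholangiocyte markers; adjusted p with an estimated correlation ran from 0.303 to 0.458. Summed hepatocyte markers came to 2208 ± 1720 CPM in control and 1342 ± 624 CPM in GOF (SD, n = 4 each), with 4618 CPM in control B. Of 18 summed marker lists of other cells 15 were lower in GOF liver and 7 were lower in 4 of 4 pairs, among them periportal hepatocyte, stellate, cholangiocyte, neutrophil and monocyte, platelet and mesothelial markers. The 18 include lists made for lung cells, so they do not count separate liver cell types. Of these, alveolar type 1, airway and alveolar macrophage markers were lower, the last in 4 of 4 pairs, and alveolar type 2 markers were higher. Exact two-sided permutation tests over the 8 libraries, which leave the pairs aside, gave no p under 0.0571 (0.0286 being the smallest possible). Mitochondrially encoded transcripts, a measure of sample quality, also moved with the genotype, from 14200 ± 3470 to 12340 ± 2620 CPM, lower in 4 of 4 pairs (permutation p = 0.429; camera adjusted p = 0.000377 in the paired fit, 0.303 with an estimated correlation).

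**Figure D1:**
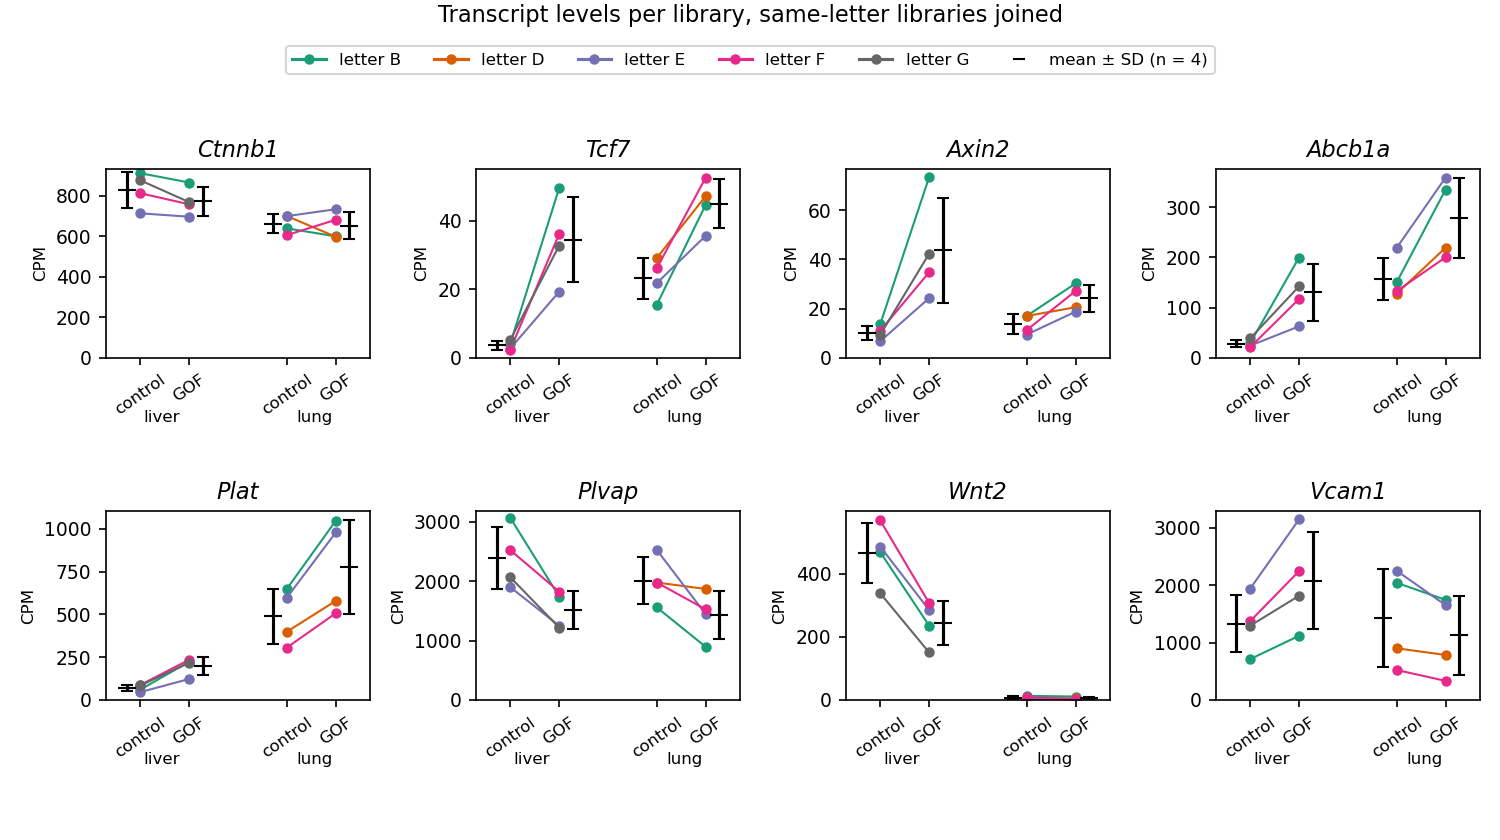
CPM values (TMM-scaled) of 8 genes in each library of liver and lung, control and GOF; lines join libraries with the same letter and black bars give the mean ± SD of the 4 libraries. Tcf7, Axin2, Abcb1a and Plat were higher and Plvap lower in GOF in all 4 pairs of each tissue, while Vcam1 was higher in 4 liver pairs and in 0 lung pairs.

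In lung endothelial cells the Wnt targets Tcf7 and Axin2 lay higher in GOF, and no gene passed the test without pairing. Tcf7 stood at 23.2 ± 5.93 CPM in control and 45.0 ± 7.08 CPM in GOF (SD, n = 4 each; paired log2 fold change 0.98 ± 0.179, SE), Axin2 at 13.7 ± 3.92 and 24.2 ± 5.43 CPM (0.84 ± 0.214) and Abcb1a at 157 ± 42.1 and 278 ± 80.2 CPM (0.81 ± 0.119), each higher in 4 of 4 pairs. In the paired fit 3 of 15641 genes passed. Serpinb1a, a protease inhibitor, rose from 68.5 ± 23.5 to 163 ± 63.4 CPM (1.22 ± 0.144). Amigo2, an adhesion protein, fell from 219 ± 48.6 to 105 ± 33.5 CPM (-1.09 ± 0.122) and Cytl1, a secreted cytokine-like protein, from 337 ± 116 to 166 ± 48.4 CPM (-1.004 ± 0.118). These 3 genes were named because the count was small; their adjusted p was 0.0113. Without pairing, edgeR called 0 genes and 341 had an unadjusted p under 0.05, where 782 were expected; DESeq2 called 11, 7 higher and 4 lower. Without pairing the count became 1 without GOF B; the paired count of 3 became 5 without the B pair and 0 without the D pair. The call of Amigo2 (-1.184 to -1.014 over its alternatives) was also lost without the F pair and that of Cytl1 (-1.077 to -0.9137) without the E pair.

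Of 17 Wnt target and feedback genes in lung, 0 passed over all genes in either fit (1 higher without pairing and 3 with it, adjusted over the list alone). A positive fold change was found for 14. Camera placed the list higher (adjusted p = 0.000216, 0.226 with an estimated correlation; in the paired fit 1.64e-05 and 0.604). Its mean log2 ratio was 0.794, 0.344 and 0.161 in pairs B, E and F and -0.221 in pair D. Of 41 central nervous system endothelial genes 0 passed, with a median log2 fold change of -0.02 and camera adjusted p = 0.463. Sox17 stood at 71.5 ± 9.79 and 116 ± 52.6 CPM (SD, n = 4 each), Cldn5 at 2167 ± 410 and 2603 ± 802 CPM, Plvap at 2009 ± 397 and 1433 ± 404 CPM and Vwf at 9677 ± 1970 and 7020 ± 1800 CPM, none past the threshold. Slc2a1 (paired log2 fold change 0.14 ± 0.147), Mfsd2a (0.67 ± 0.812), Pecam1 (-0.24 ± 0.0859) and Cdh5 (0.02 ± 0.0776) did not pass, and Lef1 was too low to be tested. Among 15 venous genes Amigo2 fell in the paired fit (1 higher and 9 lower, adjusted over the list alone), and Car8 (-0.73 ± 0.126) did not pass. Camera placed the list lower without pairing (adjusted p = 2.48e-05; 0.503 with an estimated correlation). Cell cycle genes had a positive fold change in 26 of 28 members without pairing (median 0.95; camera adjusted p = 1.29e-14, 0.448 with an estimated correlation). Interferon response genes had one in 17 of 20 (median 0.67; 6.79e-09, 0.503 with an estimated correlation), and 0 members of either list passed. Fibroblast markers (median 0.65), Kupffer cell markers, which other macrophages share (0.75), and neutrophil and monocyte markers (0.56) also lay higher in GOF lung by camera (adjusted p = 0.00026, 4.87e-05 and 0.000216; 0.503, 0.448 and 0.503 with an estimated correlation). The fibroblast sum was higher in GOF in 2 of 4 pairs, with 4321 CPM in GOF B against 1571 to 1841 CPM in the other GOF libraries, and that of neutrophil and monocyte markers rose mainly in pair B, from 930.6 to 2070 CPM, and fell in pair D. The Kupffer sum was higher in 4 of 4 pairs, most in pair B, from 56.21 to 167.6 CPM. Platelet markers summed to 971 CPM in control E and 663 CPM in GOF E, against 35.1 to 126 CPM in the other 6 lung libraries.

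**Figure D2:**
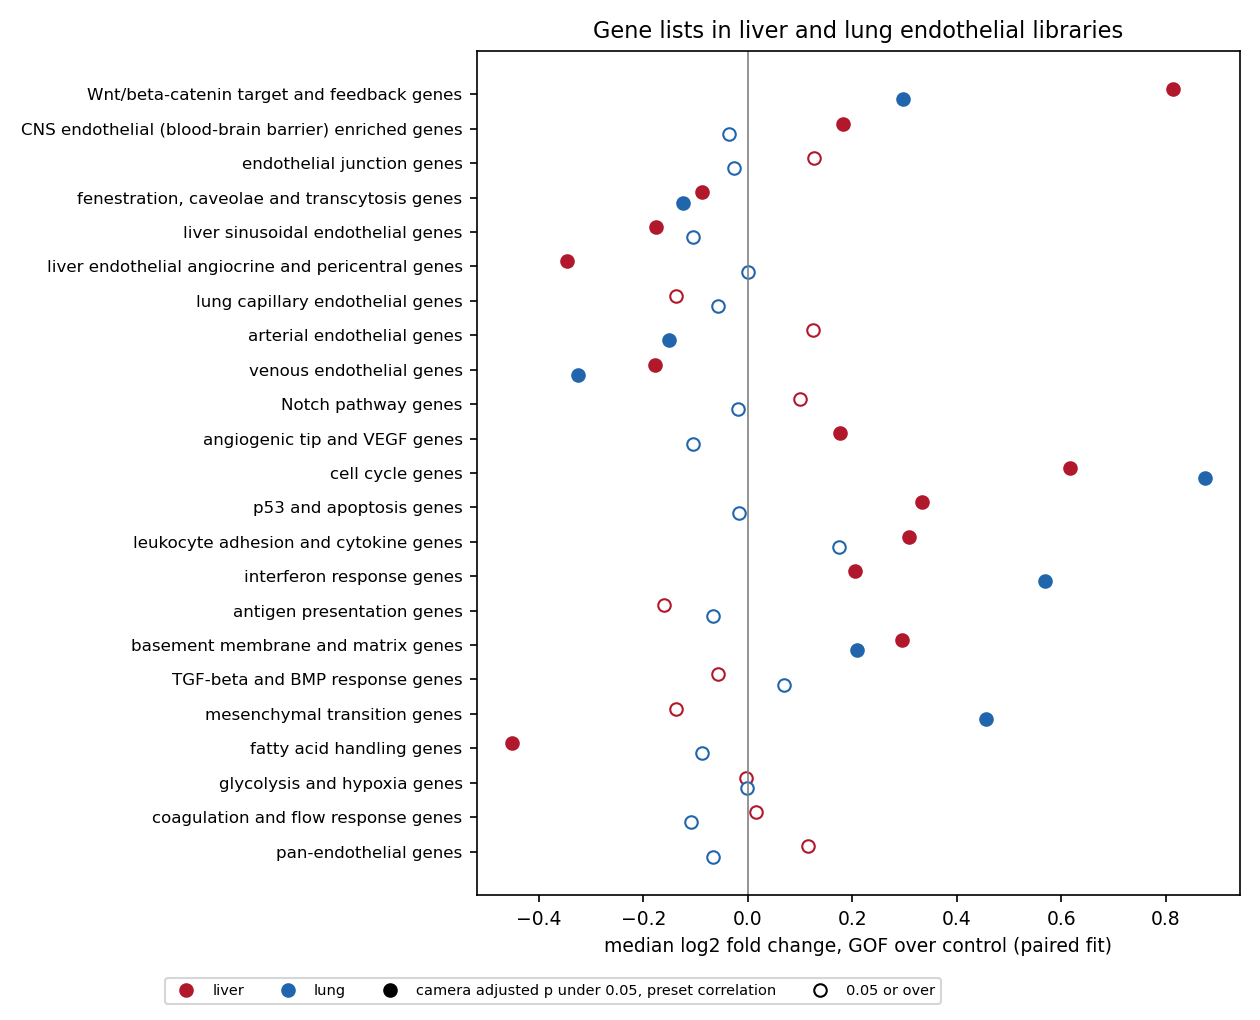
Median log2 fold change (GOF over control, paired fit) of each fixed gene list in liver (red) and lung (blue); filled points have a camera adjusted p under 0.05 with the preset correlation, none of which held with an estimated correlation. The Wnt list lay at 0.81 in liver and 0.30 in lung.

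By the interaction test, the difference between GOF and control libraries was not the same in both tissues for a set of genes. Other splits of the libraries, given below, did not exclude chance for this tissue difference. Nckap5 was raised in liver, from 0.318 ± 0.267 to 10.3 ± 4.85 CPM (SD, n = 4 each), and stood at 183 ± 32.5 and 214 ± 43.2 CPM in lung, an effect lower in lung by 4.81 ± 0.603 on the log2 scale; it was the gene past the threshold of the interaction test without pairing (adjusted p = 0.00596 among 17536 genes). In the paired fit 86 genes passed, 27 with a higher and 59 with a lower effect in lung. Dkk2 (-3.28 ± 0.368, SE, lung minus liver), Myof, a membrane-repair protein (-1.28 ± 0.127), Bmx (-1.25 ± 0.15) and Vcam1 (-1.02) had effects higher in liver. Vcam1 was higher in GOF in 4 of 4 liver pairs and lower in 4 of 4 lung pairs. Effects were higher in lung for Olfm1 (1.56 ± 0.16), which went from 224 ± 47.6 to 95.8 ± 30.1 CPM in liver and from 33.1 ± 9.82 to 40.4 ± 8.65 CPM in lung, and for Loxl1, a collagen cross-linking enzyme (2.52 ± 0.346), Krt7, a keratin of bile duct and airway epithelium (1.99 ± 0.194), and Htra1, a secreted protease (1.12 ± 0.163). Tmeff1 had 41 reads in liver control and 0 in liver GOF, and Cfi 0 in lung control and 85 in lung GOF, at least 13.3-fold lower and at least 27.5-fold higher.

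By list, 2 of 18 Wnt genes, 3 of 20 tip cell genes and 3 of 17 leukocyte adhesion genes had a lower effect in lung in the paired fit and none a higher one (4, 4 and 5 adjusted over the list alone). Camera gave adjusted p = 0.00116, 0.00116 and 0.000884 (0.243, 0.243 and 0.536 with an estimated correlation). Markers of cholangiocytes, fibroblasts and mesothelium went the other way (medians 1.74, 1.20 and 1.44; adjusted p = 6.6e-08, 6.6e-08 and 7.82e-07), and of these the cholangiocyte list held with an estimated correlation (adjusted p = 0.0393). Without pairing the count of 1 became 2 without liver control E or lung GOF E and 3 without liver GOF E, limma called 0 and DESeq2 42. The paired count of 86 became 184 without the lung E pair and 54 without the lung F or D pair.

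Across the 14366 genes tested in both tissues, log2 fold changes in liver and lung from the paired fits had a Pearson r of 0.07 (Spearman coefficient -0.00139), a correlation across genes, which are not independent replicates. Of 388 liver genes called in the paired fit and tested in lung, 216 (55.7%) had the same sign in lung. These were 118 of 239 genes higher in liver (median log2 fold change in lung -0.0023) and 98 of 149 genes lower in liver (median -0.1). No gene was called in both tissues without pairing; with it Amigo2 was called lower in both, where 0.0207 were expected (Fisher's exact test, p = 0.0206, two-sided).

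**Figure D3:**
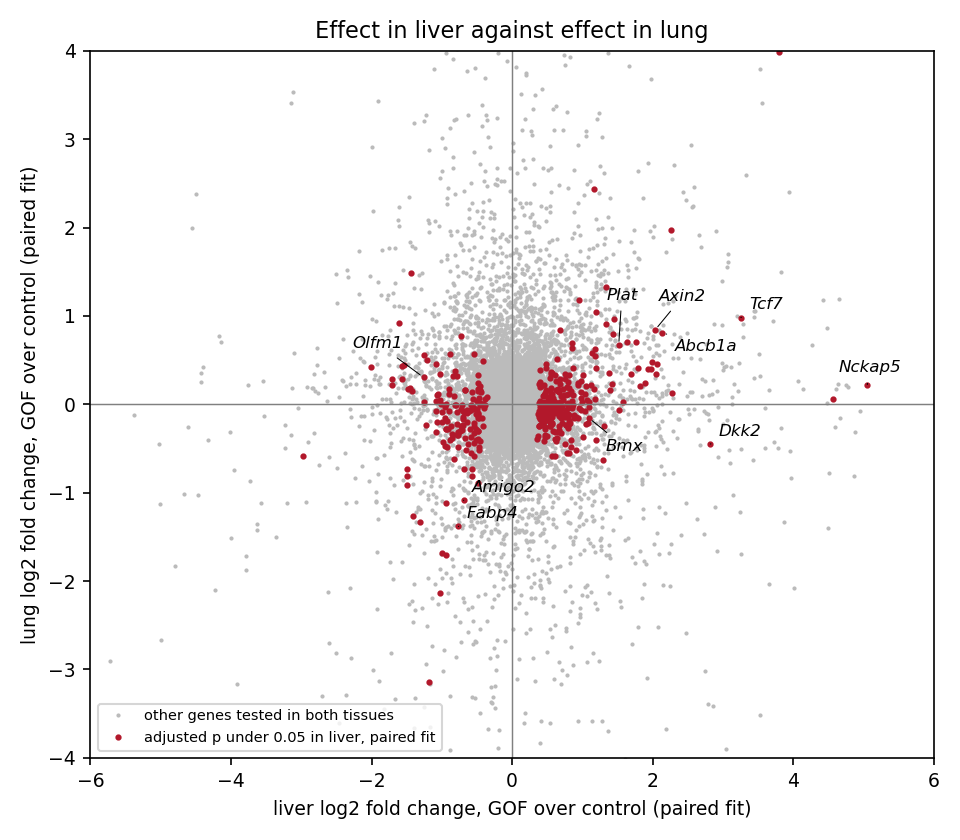
Log2 fold change (GOF over control, paired fit) in liver against lung for 14366 genes, of which 90 lie outside the axes; red points passed an adjusted p of 0.05 in the paired liver fit. Tcf7, Axin2, Abcb1a and Plat lie above 0 in both tissues, and Dkk2 above 0 in liver and below 0 in lung.

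An averaged effect over both tissues, fitted with pairs after the data were examined, was called for 133 of 14366 genes, 80 higher and 53 lower; 103 of them were also liver calls. Higher in 8 of 8 pairs were Plat (average log2 fold change 1.09 ± 0.0696, SE; 1.52 in liver and 0.67 in lung), Tcf7 (2.11 ± 0.159), Abcb1a (1.47 ± 0.13), Axin2 (1.43 ± 0.138), Sox4 (1.16 ± 0.148), Maged2, an X-linked gene (1.06 ± 0.13), Tgfb2 (0.76 ± 0.0787) and Net1 (0.74 ± 0.0705). Lower in 8 of 8 pairs were Fabp4 (-1.07 ± 0.138), Amigo2 (-0.90 ± 0.091), Car8 (-0.71 ± 0.0789), Plvap (-0.60 ± 0.0818), Cpe, a peptide-processing enzyme (-0.57 ± 0.07), and Lyve1 (-0.51 ± 0.0664). These 14 genes were chosen after their values were seen. The letters B, E and F occur in both tissues and may stand for the same mice, so the 8 pairs may not be independent. Of the 133, 121 had the same sign in both tissues and 73 had an unadjusted p under 0.05 in lung. The Wnt list was higher (4 of 16 members, 7 adjusted over the list alone; camera adjusted p = 2.05e-17, and adjusted p = 0.0186 with an estimated correlation). Without pairing 9 genes passed, 9 higher and 0 lower, and without the lung F pair 86. Among the named genes, the calls of Plat, Tgfb2, Net1, Fabp4, Amigo2, Car8, Plvap, Cpe and Lyve1 were lost without pairing.

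Control libraries of lung and liver endothelial cells differed in 3940 of 15806 genes, 2209 higher in lung and 1731 higher in liver. Lung cells carried Slc6a2, the noradrenaline transporter (at least 54700-fold over liver, where it had 0 reads), and Edil3, an integrin ligand (at least 5300-fold), and 20 of 23 lung capillary genes were higher in lung (20 adjusted over the list alone; camera adjusted p = 3.52e-26, 0.0591 with an estimated correlation). Of 24 liver sinusoidal genes 20 were lower in lung and 1 higher (21 and 1 adjusted over the list alone; 6.59e-21, 0.203 with an estimated correlation), the higher being Lyve1 at 243 ± 76.8 CPM in liver and 1650 ± 353 CPM in lung (SD, n = 4 each). Of 41 central nervous system endothelial genes 17 were higher in lung and 7 lower (18 and 7 adjusted over the list alone; 4.35e-05, 0.0608 with an estimated correlation), and 15 of 20 interferon genes were lower in lung (16 adjusted over the list alone; 1.24e-07, 0.221 with an estimated correlation). Tcf7 was higher in lung, 3.45 ± 1.28 against 23.8 ± 6.15 CPM, while Axin2 (9.78 ± 2.86 against 14.1 ± 4.16 CPM) and Plvap (2304 ± 517 against 2065 ± 399 CPM) did not pass. Epithelial transcripts of each organ were present: Alb at 1281 ± 1010 CPM in liver control, Ttr and Bhmt with 0 reads in lung control, and Sftpc, the surfactant protein of alveolar type 2 cells, at 3982 ± 3130 CPM in lung control, at least 150000-fold over liver. Cldn18 stood at 273 ± 112 CPM in lung control. Differences between the control libraries may thus include RNA of other cells. Blocked over the letters B, E and F that both tissues share, which leaves out liver G and lung D, 2104 of 15970 genes passed.

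The authors' deposited table gives 130 liver genes with an adjusted p under 0.05, 87 higher and 43 lower in GOF, led by Kif21b (log2 fold change 1.94, adjusted p = 6.19e-24). All 5 liver genes called without pairing and 117 of the 401 called in pairs were among them. For lung the authors' deposited table gives 1 gene, Maged2 (0.852, adjusted p = 0.00821). In the fit made here Maged2 stood at 51.6 ± 13.1 CPM in control and 116 ± 23.4 CPM in GOF (SD, n = 4 each), higher in 4 of 4 pairs and not past the threshold (adjusted p = 0.0841 in the paired fit).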

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

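The tests weighed here, the splits of libraries included, were chosen or read only after the result was seen; leaving out both B libraries was chosen after the hepatocyte transcripts of control B were seen and before its own outcome was.

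Libraries far from the others of their group (by Dixon's ratio of the gap to the range) numbered 25 of 268 groups of 4 libraries tested, where chance gives about 13. In liver control B, Mfsd2a was at 2.28 CPM (others 0 to 0.209), Vwf at 9050 CPM (5980 to 6470) and Net1 at 203 CPM (105 to 116); summed cholangiocyte markers came to 175 CPM (23.2 to 39.1) and mural markers to 258 CPM (67.3 to 78.6). In liver control F, Plekha6 was at 44.2 CPM (17.0 to 20.3) and fibroblast markers at 1230 CPM (314 to 343). In liver control E, Ehd3 was at 3290 CPM (2200 to 2340) and Clec4g at 1710 CPM (639 to 746). Sex-linked transcripts came to 592 CPM in liver control G and 517 CPM in lung control B. In liver GOF B, Prss23 was at 227 CPM, Cpe at 186 CPM, cholangiocyte markers at 83.6 CPM and lymphocyte markers at 16.9 CPM (others 39.4 to 41.8). In liver GOF E, Plat was at 123 CPM (217 to 235) and Maged2 at 127 CPM (175 to 183); in liver GOF G, Eda2r was at 25.7 CPM. In lung control E, Fabp4 was at 76.9 CPM (32.3 to 39.6) and platelet markers at 971 CPM (45.4 to 126), and in lung control B mural markers were at 397 CPM. In lung GOF E, Tgfb2 was at 70.2 CPM and platelet markers at 663 CPM (35.1 to 89.2); in lung GOF B fibroblast markers were at 4320 CPM, and in lung GOF D NK cell markers at 9.2 CPM.

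By the interaction test the effect differed between tissues (log2, lung minus liver) for Nckap5 by -4.81 without pairing and by -4.71 in pairs. In pairs it differed by -3.28 for Dkk2, -1.28 for Myof, -1.25 for Bmx and -1.02 for Vcam1, and by 1.99 for Krt7, 1.56 for Olfm1, 2.52 for Loxl1 and 1.12 for Htra1. The fitted 6.49 for Tmeff1 and 7.97 for Cfi rest on groups with 0 reads and depend on the prior count. The calls of Nckap5, Tmeff1 and Cfi in pairs were lost with limma trend and with quantile normalisation, and so was that of Nckap5 without pairing.

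Other splits of the same libraries bear on the counts. In liver without pairing, 2 of 35 splits called as many genes as the real 5, a share that is not under 0.05. The highest other, 14, joined B and G against E and F, which parts the sexes and keeps every pair together. It reflects a structure of the samples, so it is no chance regrouping, and the next called 1. This share therefore does not decide on chance. Among the 8 splits that part all pairs, the others called 0. With pairs, the 8 possible splits are too few for a share under 0.05; the real counts were 401 in liver and 3 in lung, 1 split of 8 reaching each, and the highest other 0 in both. In lung without pairing all 35 splits reached the real 0, and joining B and E against D and F called 753, a structure of the samples not named by the labels. For lung against liver control 1 of 35 splits reached 3940, the real one (highest other 5). This share is under 0.05 and is the smallest that 35 splits can give. For the tissue difference 17 of 100 drawn splits reached the real 1 (highest other 2), so chance was not excluded; in pairs 3 of 100 reached 86 (highest other 153), and for the averaged effect 2 of 100 reached 133 (highest other 156). These shares rest on the liver labels, since splits that flip a liver pair called at most 5 and 2 genes. Among the 11 drawn splits that keep the liver labels, the real one included, 3 reached 86 and 2 reached 133. Chance was therefore not excluded for a shared effect. For the tissue difference in pairs these splits cannot decide, since they leave the liver effect in place and a liver effect alone can give calls. The split with 153 genes flips all 4 lung pairs, which turns the tissue difference into the averaged effect, so it is no chance regrouping; the next called 100. The splits with 100 and 156 genes flipped lung B, D and F.

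Fewer genes were called in lung than in liver. Dilution of the lung libraries by RNA of other cells stays open. Summed pan-endothelial transcripts in the lung libraries were 0.925 ± 0.114 (SD, n = 8) of the liver mean. This ratio would argue against a large dilution only if endothelial cells of both tissues held these transcripts at like levels, which these libraries cannot show. For the liver calls as a set, the lung pairs did not show an effect of the size measured in liver. Signed as in liver, the 388 genes called in liver pairs and tested in lung were averaged. Their mean log2 ratio was 0.852 ± 0.0992 per liver pair and 0.107 ± 0.0988 per lung pair (SD, n = 4 each). The liver mean is raised by their selection there, by an amount not estimated. The set may also hold genes of other liver cells, which lung need not repeat. Whether a larger spread in lung hides a smaller shared effect therefore stays open. For the Wnt list alone it stays open: the mean log2 ratio of 16 Wnt genes was 0.951 ± 0.229 per liver pair and 0.27 ± 0.422 per lung pair (SD, n = 4 each; exact two-sided permutation p = 0.0571, 0.0286 being the smallest possible), which cannot be told apart with 4 pairs. A Wnt programme already more active in lung control cells is a candidate explanation (camera adjusted p of the Wnt list 0.106, 0.256 with an estimated correlation; Tcf7 was higher there), and a difference between the tissues in recombination or response stays open and untested.

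Markers of other liver cells were lower in GOF in the paired fit. Without both B libraries all 5 marker lists called lower remained so by camera with the preset correlation, so these calls did not rest on control B alone. With an estimated correlation 0 marker lists were called in the paired fit (smallest adjusted p 0.303). Summed periportal hepatocyte, cholangiocyte and mesothelial markers were higher in GOF in 0 of 4 pairs. For these lists this argues against extra RNA in another single control as the whole explanation. It stays open for hepatocyte and fibroblast markers, whose sums were higher in GOF in 1 of 4 pairs. Fibroblast markers came to 1230 CPM in control F against 314 to 343 CPM in the other controls. A lower share of all other cells stays open: 15 of 18 summed marker lists of other cells, lists made for lung cells included, were lower in GOF and 3 higher. Summed lymphocyte markers exceeded periportal hepatocyte markers in log2 ratio by 1.31 ± 0.27 (SD, 4 pairs), but Lck alone made up 80.6% of that sum, so this does not decide. A lower carry-over of particular cells in the GOF sorts, or an effect of activated beta-catenin on neighbouring cells, stays open; falls of Arg1 or Krt7 may belong to such cells, and CD31 sorting would remove most of them.

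The third pattern is the averaged effect, in which 121 of 133 called genes had the same sign in both tissues and 67 had 1 sign in all 8 pairs; Krt7, Olfm1, Dkk2 and Myof are called there with opposite signs. Beside the Cdh5 locus, whose promoter drives the Cre, 0 of 13 tested neighbours (of 20 in GRCm38.p6) were called. Their median log2 fold change was 0.04, with a range of -0.533 to 1.37. The insertion site of the Cre transgene is not given in the sources used here, so genes beside it could not be examined. Agreement by chance remains open, and 16 flips are too few for a share under 0.05: 294 genes had 1 sign in all 8 pairs, and with the liver labels kept, 3 of the 16 flips of the lung pairs gave as many, the highest 523 after flipping B, D and F; flipping all lung pairs gave 272. For the set as a whole a shared response is therefore only a hypothesis. The Wnt list was called in the averaged effect with an estimated correlation, but such a call can rest on liver alone. In lung its mean log2 ratio was 0.794, 0.344 and 0.161 in pairs B, E and F and -0.221 in pair D. Whether the Wnt list responds in both tissues stays open, and a biologist may want to follow it up.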

How the results depend on the processing

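The alternatives with the block kept, the robust test, the fits without both B or both E libraries and the averaged effect were tests chosen only after the result they vary was seen; the others were fixed before. Of the liver genes called without pairing, 5 became 401 with the replicate block, 150 with DESeq2, 12 with quantile normalisation and limma, 27 with no filter, 1 at an FDR of 0.01, 9 without both B libraries, and 1 to 12 without 1 library (1 without control E, control F or GOF G, 3 without control G or GOF F, 12 without GOF E). In lung edgeR called 0 (341 genes with an unadjusted p under 0.05, limma 0). This became 3 with the replicate block, 11 with DESeq2 and 0 to 1 without 1 library (1 without GOF B). For the tissue difference 1 became 86 with the replicate block, 42 with DESeq2, 0 with quantile normalisation and with limma trend, and 1 to 3 without 1 library (2 without liver control E or lung GOF E, 3 without liver GOF E). For the control tissues 3940 became 2104 with the replicate block over shared letters, which also leaves out liver G and lung D, and 3229 to 3944 without 1 library. In liver pairs 401 became 951 with DESeq2, 610 with limma trend, 151 at an FDR of 0.01, 988 with no filter, and 256 to 308 without 1 pair (261 without E, 256 without F). In lung pairs 3 became 117 with DESeq2, 9 with limma trend, 15 with quantile normalisation, 7 with robust edgeR, 0 at an FDR of 0.01, 84 with no filter, and 0 to 5 without 1 pair (0 without D, 5 without B). For the tissue difference in pairs 86 became 388 with DESeq2, 21 at an FDR of 0.01, 229 with no filter, and 54 to 184 without 1 pair (54 without lung F or lung D, 184 without lung E). For the averaged effect 133 became 442 with DESeq2, 46 at an FDR of 0.01, 294 with no filter, 9 with no replicate block, and 86 to 118 without 1 pair (86 without lung F). The overlap of liver and lung calls went from 0 to 1 with the replicate block. With an estimated correlation the Wnt list went to an adjusted p of 0.206 in liver and 0.226 in lung, and the list of central nervous system endothelial genes to 0.338 in liver and 0.165 for the averaged effect. Without 1 library the Wnt list lay between 9.56e-15 and 1.79e-06 in liver and between 3.34e-05 and 0.00628 in lung, and the central nervous system list between 0.00268 and 0.209 in liver and between 0.236 and 0.778 in lung. For the averaged effect without 1 pair they lay between 2.58e-18 and 1.48e-14 and between 0.00421 and 0.046. Some genes that were not called turned their sign. Slc2a1 in liver went to -0.02477 with the replicate block, -0.01775 with quantile normalisation, -0.02634 with limma trend, -0.04891 without both B libraries, and from -0.1314 to 0.1577 without 1 library (in pairs -0.1034 to 0.0843). Ctnnb1 in lung went to 0.0353 with quantile normalisation, with and without the block, and from -0.0783 to 0.02213 without 1 library (in pairs -0.09136 to 0.04836). Without 1 library Mfsd2a went from -0.4105 to 3.441 in liver and from -0.7798 to 0.7793 in lung (in pairs -0.1562 to 1.167), Cdh5 in lung from -0.07174 to 0.1129, and Plvap between control tissues from -0.2855 to 0.01026.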

Other observations

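Chromosomal sex differed between pairs and not within them: B and G in liver and B and D in lung had Xist between 211 and 654 CPM, and E and F in both tissues had summed Y-linked transcripts between 169 and 229 CPM. Of the female libraries, lung GOF D had summed Y-linked transcripts at 2.15 CPM and the others at 0.0733 to 0.309 CPM. The source of these reads in lung GOF D was not examined. Genotypes were thus balanced for sex in both tissues, with 2 female and 2 male pairs in each. The 3 letters that occur in both tissues had the same sex in both.

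Control libraries of the tissues differed in groups not described so far. Summed neutrophil and monocyte markers came to 1274 ± 684 CPM in lung control and 156 ± 44 CPM in liver control (SD, n = 4 each). RNA of such cells was not told apart from that of endothelial cells in these differences. Of 14 antigen presentation genes 6 were higher in lung and 1 in liver (6 and 1 adjusted over the list alone; camera adjusted p = 0.0416, 0.512 with an estimated correlation), and of 20 tip cell and VEGF genes 8 were higher in lung and 3 in liver (9 and 3 adjusted over the list alone; 0.00178, 0.223). Of 17 angiocrine and pericentral endothelial genes 9 were higher in liver and 2 in lung (9 and 2 adjusted over the list alone; 9.51e-12, and adjusted p = 0.0186 with an estimated correlation). Arterial genes moved both ways, 7 of 21 higher in each tissue (10 and 8 adjusted over the list alone).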
